A study of Mus musculus with 36 samples.

How the data were processed

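The samples were single-nucleus RNA libraries from 36 mice, 1 library per mouse, in 4 groups by labelled Myt1l genotype and sex: 6 heterozygous females, 10 heterozygous males, 10 wild-type females and 10 wild-type males. Per the labels, tissue from the tuberal hypothalamus with neighbouring thalamus was taken 30 minutes after a session of a social operant task, frozen, and later turned into nuclei by douncing and an iodixanol gradient. Per the labels, the nuclei were barcoded with a ScaleBio kit, and isolated in 9 batches of 4 mice balanced for sex and genotype. With 6 mice in 1 group and 10 in each of the others, not every batch can have held 1 mouse of each group. The labels do not say which mouse was in which batch, so batch could not enter any fit. Groups were taken from the labels, and the mouse was the replicate throughout.

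The authors deposited, per the file headers, 1 matrix of genes by nuclei per mouse, and its values are expected counts: most entries are whole numbers of UMIs, and some are fractions such as 0.5, as arise when reads that fit several genes are shared out among them. The design of the tests had assumed whole UMI counts, so sums per mouse and cell class were rounded to whole counts before the count models. Per the submitters' processing notes the genome build was mm10, and Seurat 4.3.0 was named with no role. The aligner, the counter and the calling of nuclei are not given in the sources used here, nor is whether counting used the strand, so a gene and an overlapping antisense partner, such as Xist and Tsix, cannot be told apart. For a pair of mice the column order served as the nucleus name, because no barcode list was used. Gene names are those paired with the Ensembl IDs in the files. Chromosomes and coordinates came from a GENCODE annotation of the same build, in which 55154 of 55335 gene IDs matched without their version number.

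The matrices held 246984 barcodes, with a median of 1406 UMIs. Of these, 172546 had at least 500 UMIs, and 8828 barcodes above 10000 UMIs, which hold 44.5% of all UMIs, were left out as possible groups of nuclei. Nuclei with more than 5% mitochondrial UMIs were left out. The doublet caller Scrublet, as built into scanpy 1.11.5, marked 9 nuclei at its own threshold (0.00534%). Whether doublets had been removed before deposit is not given and was not tested. The 5% of nuclei with the highest doublet scores in each mouse were removed instead, 7253 in all, and keeping them was an alternative. All 168463 nuclei of up to 20000 UMIs were clustered together, and 156463 of them were kept for the comparisons. The total per mouse was 9301179 to 48132532 UMIs in all barcodes and 5290103 to 25608432 UMIs in 2620 to 9685 kept nuclei.

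Nuclei were clustered with scanpy 1.11.5 and the Leiden method of igraph 0.11.9 in Python 3.11.15, on 40 principal components of 3000 variable genes with 20 neighbours. Neurons were clustered again on 50 components at a resolution of 2.0. Myt1l, immediate early genes, genes of the Y chromosome, genes that escape X inactivation and mitochondrial genes were left out of the clustering. Cell types were named "-like" from 36 marker lists fixed before the data were examined. The thresholds that turn marker levels into a name, and that set mixed clusters aside, were set after the clusters had been seen and revised once, before any comparison of genotype or sex. Mixed clusters held 31031 of the kept nuclei, on average 20.7% in heterozygous females, 20.3% in heterozygous males, 19.6% in wild-type females and 19.2% in wild-type males. Microglia had been planned as a class, but they and vascular cells fell in mixed clusters, and ependymal-like cells were too few for the fits, so none of these was tested for single genes.

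Expected counts were summed per mouse in all kept nuclei and in 7 classes with at least 20 nuclei in at least 5 mice of each genotype, and in neuron clusters by the same rule. Each sum was tested with edgeR 4.0.16 in R 4.3.3 by the two-sided quasi-likelihood F test with TMM scaling, the package's own filter on low counts and Benjamini-Hochberg adjustment, with genotype and sex in the model, and with their product for the interaction. Every adjusted p of a single gene is edgeR's unless DESeq2 1.42.0 is named. A gene passed at an adjusted p under 0.05. Log2 fold changes are heterozygous over wild type, or female over male, with their standard error (SE). The text names Myt1l in every class where it passed the filter, and per fit the 10 higher and 10 lower genes with the smallest adjusted p past 0.05, leaving out predicted gene models unless fewer than 10 others passed; genes of the sex chromosomes that passed in all nuclei are not repeated by class. It also names up to 4 members of each fixed list that passed and, where no gene passed, the 3 with the smallest p.

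A set of 26 gene lists, also fixed before the data were examined, was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over lists and classes of 1 contrast, with camera at an estimated correlation and fry beside it. Shares of nuclei, Myt1l in CPM (counts scaled to the total of the mouse) and the mean of the immediate early list were compared by two-sided permutation tests with 100000 resamples within the other factor. CPM of genes tested in edgeR and of the spread between mice were scaled with TMM, and other CPM to the total alone. Cluster sizes were tested in edgeR with the neurons of each mouse as the library size. For shares of nuclei with a UMI, nuclei were thinned to 500 UMIs. The spread between mice was the SD of log2 CPM (prior count 2) after sex and genotype, set against genes of like expression and, for lists, against 10000 random lists. Every count of genes, but for a fit of all neurons together, was also recomputed for other splits of the mice into groups of the same sizes.

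The gene fits were tested on simulated counts with 200 changed genes, and the tests of cluster sizes, lists, spread and values per mouse on simulated sets of their own. In the simulation of all nuclei the genotype fit recovered 55.2%, 86.6% and 98.5% of genes changed 1.25, 1.5 and 2 times, and in thalamic-like neurons 46.3%, 88.1% and 97.0%. Alternatives covered the scaling, the low-count filter, the UMI limits, the doublets, the minimum of nuclei, covariates for age, depth and thalamic share, each sex alone, the mouse number as a block, DESeq2 1.42.0, the clustering resolution, and each mouse left out in turn. The filter on low counts follows the design, so fits with a covariate test somewhat different genes. A fit without 2 mice whose thalamic tissue stood apart was added after seeing the data.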

Results

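RNA of single nuclei was measured in the tuberal hypothalamus and neighbouring thalamus of 36 mice of a line that carries an edited Myt1l allele, taken 30 minutes after a social operant task. Myt1l is a zinc finger transcription factor of neurons, and the title of the series names differences between individual mice in hypothalamic neurons and social motivation. The mice were 54 to 77 days old and fell into 4 groups by labelled genotype and sex: 6 heterozygous females, 10 heterozygous males, 10 wild-type females and 10 wild-type males. No mouse without the task was among them. The libraries held 9301179 to 48132532 UMIs each, and the kept nuclei of a mouse numbered 2620 to 9685. The median UMI count per nucleus was 2189 ± 183 (SD, n = 6) in heterozygous females, 2060 ± 270 (n = 10) in heterozygous males, 2232 ± 284 (n = 10) in wild-type females and 2190 ± 249 (n = 10) in wild-type males. Levels of Xist and of Y-linked genes matched the labelled sex in all 36 mice.

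GABAergic-like neurons were the most frequent named class, with 54307 nuclei and 35.3% ± 6.54 (SD, n = 36 mice) of the nuclei of a mouse. Glutamatergic-like neurons outside the thalamus made up 17.5% ± 3.29, and thalamic-like glutamatergic neurons, led by Prkcd, Lef1, Adamts19, Trpm6 and Tll1 in their clusters, 8.72% ± 3.08. Oligodendrocyte-like cells made up 9.51% ± 4.35, astrocyte-like cells 3.08% ± 1.27 and oligodendrocyte precursor-like cells 2.41% ± 0.716. Among 59 neuron clusters, some carried the leading genes of known populations, such as Avp and Sim1 of the paraventricular and supraoptic nuclei, Hdc of histamine neurons, Pmch of melanin-concentrating hormone neurons, and Drd2, Adora2a and Penk of striatal or amygdalar neurons. Clusters that mixed markers of several types held 31031 nuclei and were kept out of the classes.

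The first comparison checked the genotype labels by Myt1l itself (ENSMUSG00000061911.15, chromosome 12, 29528384 to 29923213 of mm10), since an altered allele can lower the amount of its RNA. Myt1l was not lower in the mice labelled heterozygous: it stood at 838 ± 79.2 CPM (SD, n = 16) in them and at 795 ± 56.1 CPM (n = 20) in wild-type mice. The difference within sex was 39.98 CPM (two-sided permutation test, p = 0.0859). By group it was 839 ± 89.6 CPM (n = 6) in heterozygous females, 837 ± 77.4 (n = 10) in heterozygous males, 770 ± 52.1 (n = 10) in wild-type females and 820 ± 50.3 (n = 10) in wild-type males, from 4011 to 22215 counts per mouse. Within neurons alone the difference was 50.4 CPM (permutation p = 0.0292), 911 ± 79.0 against 859 ± 52.2 CPM. The log2 fold change of Myt1l was 0.06 (SE 0.04, adjusted p = 0.846) in all nuclei, 0.06 (SE 0.05) in GABAergic-like neurons, 0.09 (SE 0.03) in glutamatergic-like neurons outside the thalamus and 0.08 (SE 0.04) in thalamic-like neurons. In these 3 classes the adjusted p was 0.935, 0.829 and 0.561. It was 0.41 (SE 0.20) in oligodendrocyte-like cells and -0.04 (SE 0.09) in precursor-like cells, neither past the threshold, and above 0 in 39 of 42 neuron clusters. Summed counts per gene do not show which allele or exon the RNA came from, so they check the labels only as far as the edit lowers the amount of RNA. The groups are therefore called mice labelled heterozygous below, and every direction by genotype rests on those labels.

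**Figure D1:**
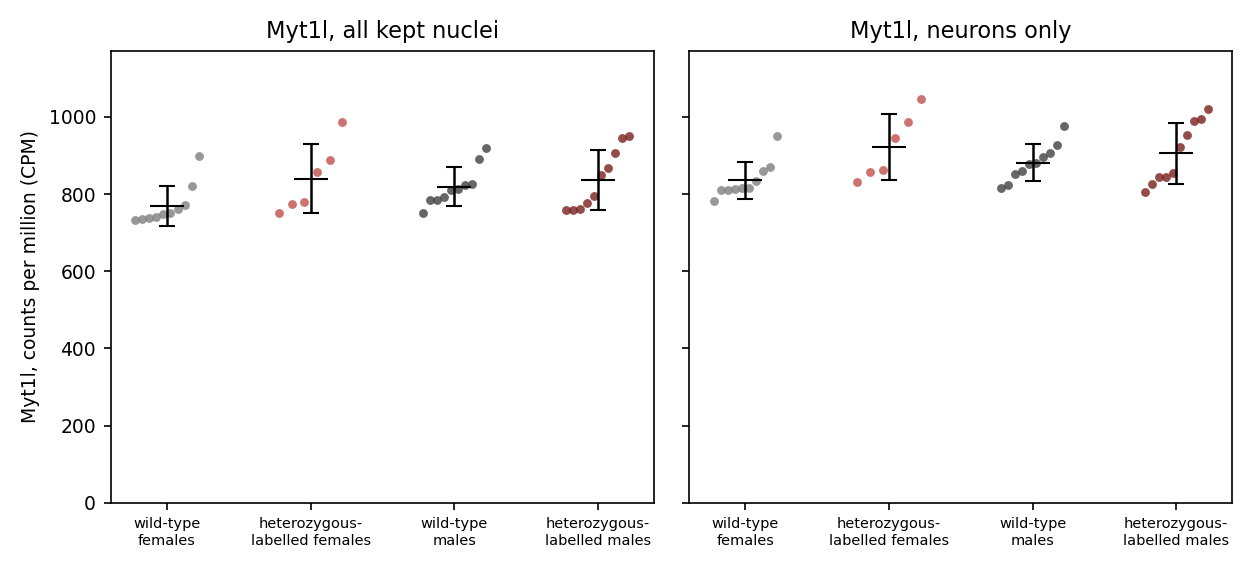
Myt1l in CPM, in all kept nuclei (left) and in neurons (right), 1 point per mouse, in the 4 groups by labelled genotype and sex, with the mean and SD of each group. The group means in all nuclei lie between 770 and 839 CPM. The mice labelled heterozygous do not lie below the wild-type mice.

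The share of each cell class was compared to ask whether genotype or sex went with a different makeup of the tissue. No class differed by genotype after adjustment over 9 classes (two-sided permutation tests). The smallest p was that of ependymal-like cells, at 0.348% ± 0.223 (n = 16) in mice labelled heterozygous and 0.222% ± 0.197 (n = 20) in wild-type mice (p = 0.0588, adjusted p = 0.344, above the wild-type median in 12 of 16). GABAergic-like neurons made up 34.6% and 35.8% (p = 0.490), and p was 0.789 for thalamic-like neurons and 0.950 for oligodendrocyte-like cells. Between the sexes, oligodendrocyte precursor-like cells made up 2.64% in females and 2.22% in males (p = 0.0844, adjusted p = 0.326), and committed precursor-like cells 0.577% and 0.480% (p = 0.0833), neither past the threshold. The share of thalamic-like cells among neurons varied widely within each group, with means of 12.8% ± 6.73, 14.6% ± 4.39, 15.4% ± 4.95 and 11.5% ± 3.59 in heterozygous females, heterozygous males, wild-type females and wild-type males. Of 52 neuron clusters large enough to test, none differed in size by genotype or sex (edgeR, 3 and 8 clusters at an unadjusted p under 0.05). With TMM factors on the library size, 1 cluster differed by sex, GABAergic-like cluster 10 (adjusted p = 0.0482).

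**Figure D2:**
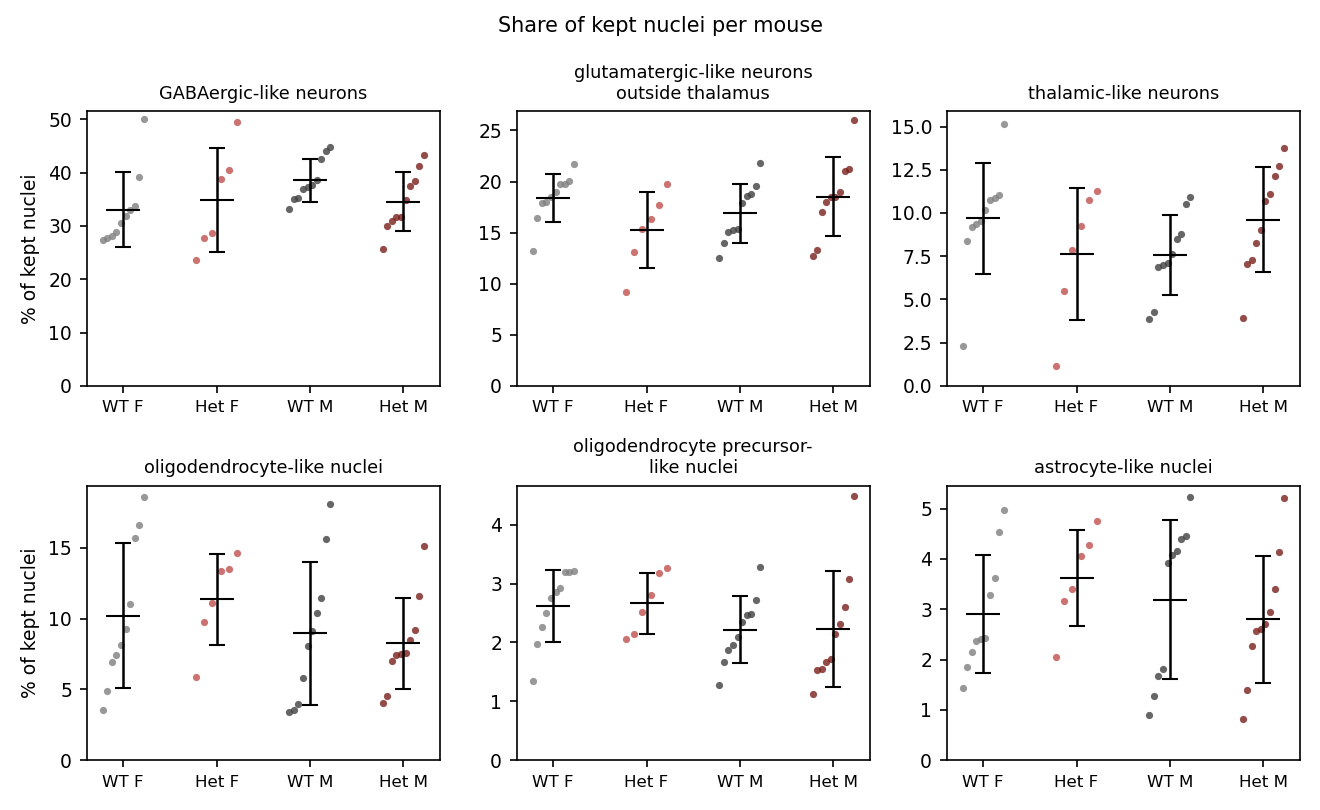
Share of kept nuclei in 6 cell classes, in percent, 1 point per mouse, in the 4 groups (WT, wild type; Het, labelled heterozygous; F, female; M, male), with mean and SD. The groups overlap in every class, and none passed the test by genotype or by sex.

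The effect of the labelled genotype was then tested gene by gene, first in all nuclei. Adamts6, a secreted metalloprotease (chromosome 13, 104287835 to 104496695), rose by 0.20 on the log2 scale (SE 0.04, adjusted p = 0.0415, higher in 15 of 16 mice labelled heterozygous than the wild-type mean). Brinp3, a neural gene induced by BMP and retinoic acid (chromosome 1, 146494760 to 146902472), fell by 0.15 (SE 0.03, adjusted p = 0.0415) and lay below the wild-type mean in every one of the 16. In GABAergic-like neurons Zbtb20, a transcriptional repressor of the developing brain (chromosome 16, 42875881 to 43642602), rose by 0.22 (SE 0.04, adjusted p = 0.0152) and was higher in 16 of 16. These were the only genes past the threshold of 17755 tested in all nuclei and 13589 in GABAergic-like neurons, where 1151 and 841 had an unadjusted p under 0.05. DESeq2 called 23 and 17 genes, mostly lower ones (18 and 14), and with the share of thalamic neurons as a covariate edgeR called 24 in all nuclei. Leaving out 1 mouse at a time gave 0 to 5 genes in all nuclei, and leaving out wild-type female 6 and heterozygous-labelled female 5, which had little thalamus, gave 6 there and 6 in GABAergic-like neurons. With the mouse number as a block neither gene passed in all nuclei. Adamts6 lost its call with another scaling (adjusted p = 0.0534) and with age as a covariate (adjusted p = 0.0653), and Zbtb20 in females alone (adjusted p = 0.998). In GABAergic-like neurons 3 of 41 splits of the mice, the real one included, called as many genes. All neurons were also fitted together, without alternatives or other splits and with no gene named here. That fit called 4 of 16090 genes by genotype, 2 higher and 2 lower, and 27 by sex.

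In glutamatergic-like neurons outside the thalamus no gene passed in edgeR (679 of 12033 at an unadjusted p under 0.05; DESeq2 called 2). The smallest p values there belonged to Adamts6, with a log2 fold change of 0.38 (SE 0.07, adjusted p = 0.0689), and to Lrp1b, a lipoprotein receptor relative, with -0.15 (SE 0.03, adjusted p = 0.119). Next was Lars, a leucyl-tRNA synthetase, at 0.19 (adjusted p = 0.269). None passed in oligodendrocyte-like cells either, where Hnrnpr stood at -0.23, Pakap at 0.33 and Map2 at 0.25 (adjusted p = 0.780 each), nor in precursor-like cells, where Bcl6 stood at -0.66, Scd2 at 0.40 and Frmd4a at 0.30 (0.560). Purg at 0.60, Sf1 at -0.56 and Rapgef3 at 0.37 led in astrocyte-like cells, and Dcaf6 at 0.81, Birc6 at -0.54 and Cdc37l1 at -0.53 in committed precursor-like cells, none past the threshold. In these 4 glial classes edgeR counted 279, 73, 97 and 14 genes at an unadjusted p under 0.05, in the order oligodendrocyte, precursor, astrocyte and committed precursor, and DESeq2 called 0 in each.

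Thalamic-like neurons held most of the genotype calls, 26 of 9533 genes, 10 higher and 16 lower in the mice labelled heterozygous, and 24 of them off the sex chromosomes. Leaving out 1 mouse at a time gave 17 (without wild-type male 8) to 33. Among the lower genes, the Slit receptor Robo1 (chromosome 16, 72308306 to 73046095) fell by 0.21 (SE 0.04, adjusted p = 0.00626). It stood at 5478 ± 482 CPM in wild-type and 4649 ± 524 in heterozygous-labelled males (SD, n = 10 each), and at 5819 ± 473 (n = 10) and 5152 ± 432 (n = 6) in females. The adhesion phosphatase Ptprd fell by 0.19, the ephrin receptor Epha6 by 0.18, the giant cadherin Fat3 by 0.20, F-spondin (Spon1) by 0.36 and the netrin receptor Neo1 by 0.18. Unc13b, which primes synaptic vesicles, fell by 0.26 (SE 0.05, adjusted p = 0.00532) and was below the wild-type mean in all 16 mice. The protease Tll1 (chromosome 8, 64014931 to 64206271) fell by 0.76 (SE 0.13, adjusted p = 0.00343) and the splicing factor Rbm20 (chromosome 19, 53677306 to 53867080) by 0.68 (SE 0.12, adjusted p = 0.00343). The nuclear factor Tox fell by 0.29 and protein kinase C eta (Prkch) by 0.23.

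The higher thalamic genes were led by R-cadherin (Cdh4, chromosome 2, 179442431 to 179899373), which rose by 0.33 (SE 0.06, adjusted p = 0.00782, 15 of 16 mice), and by Cfap74, a gene of cilia, with 0.26 (SE 0.05, adjusted p = 0.00782). Sorcs3, a sorting receptor of neurons, rose by 0.25, palladin (Palld), which binds actin, by 0.29, and adenosine kinase (Adk) by 0.18. The chromatin genes Cxxc1 and Hdac8 rose by 0.51 and 0.19, the mitochondrial Apool by 0.53, cyclin C (Ccnc) by 0.22 and the RNA 6330411D24Rik by 0.63, with adjusted p from 0.0267 to 0.0498. Tll1 and 9330185C12Rik, which also fell (-0.54), are leading genes of 1 thalamic cluster, as is Gm19303 (-0.50). RNA of oligodendrocytes made up an estimated 0.386% of the thalamic-like nuclei in mice labelled heterozygous and 0.2999% in wild-type mice. DESeq2 called 46 genes there, 13 higher and 33 lower, and the fit without a low-count filter 55, 35 higher and 20 lower. Of 20 thalamic genes followed over the alternatives, DESeq2 lost 3 (Rbm20, Cxxc1 and Apool) and the fit without a filter 4 (Cxxc1, Ccnc, 6330411D24Rik and Fat3). With the mouse number as a block 11 lost it, Cfap74, Palld, Adk, Hdac8, Prkch, Spon1 and Epha6 among them. Ccnc kept its call in 5 of 14 fits and lost it, among others, with age and with depth as a covariate. Males alone gave 7 genes and females alone 4, and of the 20 genes 16 and 19 did not pass there. Also, 1 other split of the same mice into groups of the same sizes called 56.

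**Figure D3:**
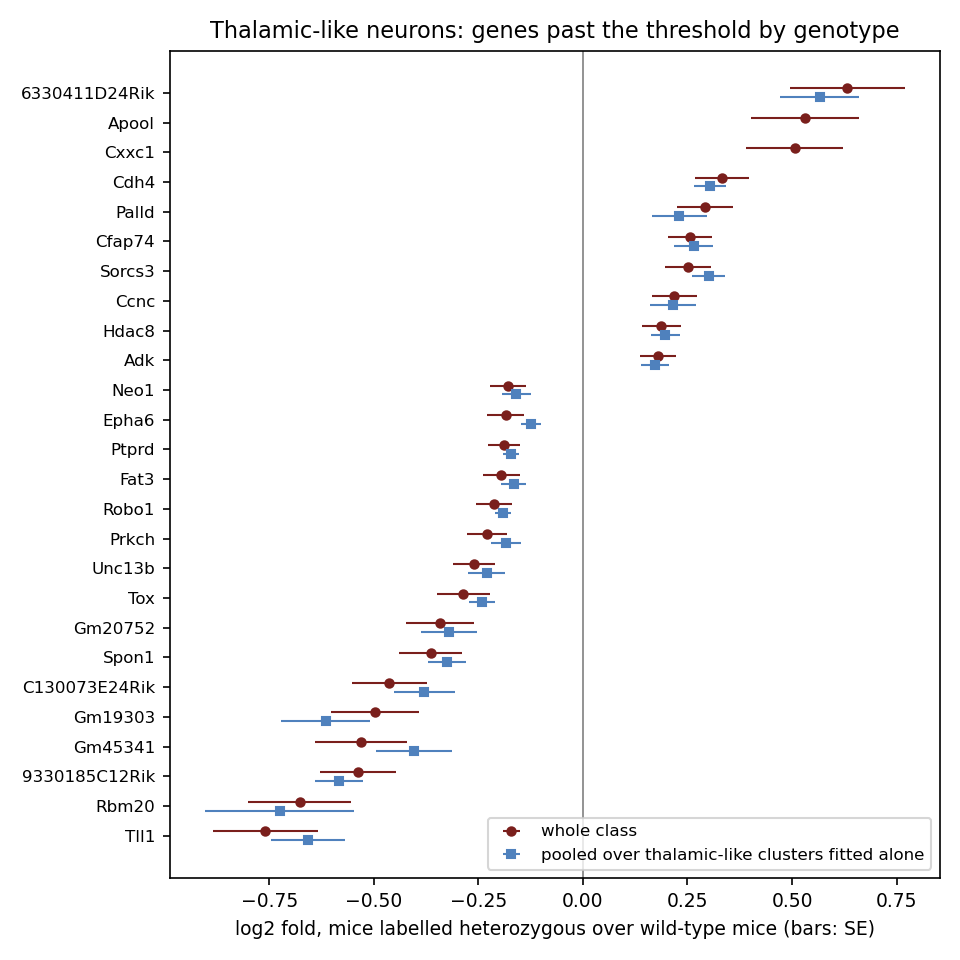
Log2 fold change of the 26 genes past the threshold by genotype in thalamic-like neurons, mice labelled heterozygous over wild-type mice, with SE: circles give the fit of the whole class and squares the pooled value of the thalamic-like clusters fitted alone. Of 21 genes tested in more than 1 cluster, 20 kept 1 sign in every one, and Tll1, Gm19303 and 9330185C12Rik are leading genes of a thalamic cluster.

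Neurons were next compared cluster by cluster, at the resolution that the series title points to. Over 42 clusters edgeR made 114 calls on 89 genes in 18 clusters, 40 higher and 74 lower in the mice labelled heterozygous, of 145704 tests. All 5 thalamic-like clusters held calls, 63 in all, against 31 in 6 of 14 glutamatergic-like clusters outside the thalamus and 20 in 7 of 20 GABAergic-like clusters. Single clusters carried these totals: thalamic-like clusters 17 and 20 held 34 and 18, and cluster 18, outside the thalamus, held 24. Adjusted within each cluster, Robo1 fell in 4 clusters and Lrp1b in 3, while Sorcs3 rose in 4, Cdh4 in 3 and the transcription factor Tshz2 in 3. Each of the 18 genes called in several clusters kept 1 direction in its calls. Over all clusters tested, called or not, Robo1 was lower in 27 and higher in 15 of 42, and Sorcs3 was higher in 25 and lower in 17 of 42. The clusters come from the same mice, so such repeats are not independent. Zbtb20 was higher in 37 of 42 clusters, Cdh4 in 32 of 39 and Tshz2 in 32 of 40, and Brinp3 was lower in 38 of 42 and Lrp1b in 36 of 42. Adjusted over all clusters together, 59 calls passed.

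Further genes passed in single clusters. In cluster 18, a glutamatergic-like cluster led by Col12a1, Robo1 fell by 0.28, the serotonin receptor Htr2c by 0.39 and the adhesion gene Alcam by 0.33, and Zbtb20 rose by 0.30. In thalamic-like cluster 17 the netrin receptor Unc5c fell by 0.21, the glutamate receptor genes Grin3a and Grik2 by 0.28 and 0.17 and Foxp2, a gene of speech and motor circuits, by 0.20, while Tshz2 rose by 0.44. The semaphorin Sema3e fell by 0.77 in thalamic-like cluster 3, and Csmd2 and the Rac regulator Chn2 rose by 0.74 and 0.56 in cluster 20. Adk fell by 0.66 (SE 0.09, adjusted p = 6.49e-07) in cluster 30, which carried Drd2, Adora2a and Penk, the reverse of its direction in thalamic-like neurons; the difference between these classes was not tested. When adjusted over all clusters, Tshz2 (0.0512), Grik2 (0.0870), Foxp2 (0.0880) and Grin3a (0.108) did not pass in cluster 17. In the Drd1 cluster 32 the metabotropic receptor Grm3 fell by 0.42. Myt1l itself passed in 1 cluster, the thalamic reticular-like cluster 22, where it rose by 0.22 (SE 0.05, adjusted p = 0.0496), and it did not pass there when adjusted over all clusters (0.0562).

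Of 26 gene lists in 8 classes, 11 of 145 list tests passed by genotype with camera at the preset correlation, and none with an estimated correlation or with fry. In all nuclei 22 of 28 synapse adhesion and scaffold genes were lower in the mice labelled heterozygous (adjusted p = 0.000851; adjusted p = 0.381 with an estimated correlation), 1 of them past the threshold when adjusted over the list alone. The glutamate receptors (17 of 24 lower), GABA receptors (13 of 16 lower) and neurodevelopmental disorder genes (24 of 31 lower) went the same way, each at an adjusted p of 0.0335. With an estimated correlation their adjusted p was 0.428, 0.381 and 0.482. Glutamate receptors (21 of 24 lower) and disorder genes (24 of 30 lower) passed again in GABAergic-like neurons at 0.0335 (adjusted p = 0.482 each with an estimated correlation), and synapse adhesion genes in precursor-like cells (13 of 15 lower, 0.0335; 0.271). Myelin genes were higher in all nuclei (19 of 20, adjusted p = 0.00214; adjusted p = 0.636 with an estimated correlation). They were also higher in glutamatergic-like neurons outside the thalamus (11 of 12, 0.000734; adjusted p = 0.409 with an estimated correlation) and in thalamic-like neurons (4 of 4, 0.0335; 0.409). Adjusted over the list alone, 3 and 2 of them passed there. Myelin is made by oligodendrocytes, whose RNA made up the shares of thalamic-like nuclei given above. Of 41 splits of the mice, the real one included, 11 passed as many list tests as the real one. The MYT1 family (Myt1l, Myt1 and St18) was higher in glutamatergic-like neurons outside the thalamus (3 of 3, adjusted p = 0.0335, and 0.271 with an estimated correlation). St18 is also among the oligodendrocyte markers used here, and RNA of oligodendrocytes was not estimated in these neurons.

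The other 20 lists did not pass by genotype in any class. They were the immediate early, immature neuron, Notch and Wnt, neuropeptide, neuropeptide and hormone receptor, monoamine, potassium channel, sodium and calcium channel, synaptic vesicle, oxidative phosphorylation, mitochondrially encoded, ribosomal, heat shock and stress, glial activation, circadian, imprinted, thalamic neuron, X-escape, Y-linked, and choroid plexus and pituitary lists. In thalamic-like neurons 18 of 28 synapse adhesion genes were lower (adjusted p = 0.0755), with Ptprd past the threshold over all genes. Unc13b was the 1 synaptic vesicle gene past it in a list split evenly in direction (11 of 23 higher, adjusted p = 0.756). No single member of any other list passed by genotype over all genes in all nuclei or in a class.

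Sex was compared as the second labelled factor. In all nuclei 27 genes passed, 19 higher and 8 lower in females, and 12 of them lie off the sex chromosomes. Xist, the RNA that silences an X chromosome, and the Y genes Uty, Ddx3y, Kdm5d and Eif2s3y parted the sexes completely, with log2 fold changes of 8.14, -7.06, -6.26, -5.92 and -8.34. Tsix, antisense to Xist, stood at 3.34 and the Y-linked Gm29650 at -7.44. Genes that escape X inactivation were higher in females by less: Kdm6a by 0.48 (SE 0.03, adjusted p = 1.17e-17), Ddx3x by 0.41, Kdm5c by 0.33, Eif2s3x by 0.48, Jpx by 0.25 and Pbdc1 by 0.20. Off the sex chromosomes Greb1, a target of oestrogen and androgen receptors (chromosome 12, 16670615 to 16800886), fell by 0.94 in females (SE 0.09, adjusted p = 3.91e-10, below the male mean in 16 of 16). It stood at 10.6 ± 2.15 CPM in males and 6.16 ± 1.22 in females labelled heterozygous (n = 10 and 6). In wild-type mice it stood at 10.97 ± 2.14 and 5.22 ± 0.865 CPM (n = 10 each). Cfap299 (chromosome 5, 98329304 to 98802047) rose by 0.53 (SE 0.06, adjusted p = 8.32e-08), Socs2, which damps growth hormone signalling, by 0.35, and Vstm2b, which did not pass with the mouse number as a block, and the Polycomb gene Pcgf2 fell by 0.24 and 0.21. Greb1 is a leading gene of 1 GABAergic-like cluster and Cfap299 of another.

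By class, GABAergic-like neurons had 23 genes by sex, glutamatergic-like neurons outside the thalamus 15, thalamic-like neurons 10 and oligodendrocyte-like cells 11, of which 10, 3, 3 and 3 lie off the sex chromosomes. In GABAergic-like neurons Esr1, the oestrogen receptor alpha gene, rose in females by 0.38 (SE 0.08, adjusted p = 0.0193, 14 of 16), Socs2 by 0.44 and Cfap299 by 0.62, and Greb1 and the BMP receptor Bmpr1b fell by 1.14 and 0.60. Esr1 did not pass without the low-count filter, nor did Esr1 and Socs2 with the mouse number as a block. Pdgfc, a growth factor, fell by 0.34 (adjusted p = 0.0155) and the microRNA host RNA Mir99ahg and the RNA Gm41804 rose by 0.18 and 0.56 in glutamatergic-like neurons outside the thalamus, as did the X-linked 5530601H04Rik by 0.29. Mir99ahg and 5530601H04Rik did not pass with depth or the thalamic share as a covariate. In thalamic-like neurons the calcium channel Itpr2 fell by 1.07 (SE 0.20, adjusted p = 0.00564) and Cntnap3 by 0.55, and the exchanger Slc24a3 rose by 0.18; Cntnap3 and Slc24a3 did not pass with depth as a covariate, and none of the 3 passed with the mouse number as a block. In oligodendrocyte-like cells the potassium channel Kcnk13 and Nkain2 rose by 0.29 and 0.15 (adjusted p = 0.0380 each, 16 of 16) and the circadian repressor Nr1d2 fell by 0.42 (adjusted p = 0.0472). These 3 did not pass with depth or the thalamic share as a covariate, and Nr1d2 not in DESeq2. Over the alternatives Kcnk13 kept its call in 8 of 12 fits, Nkain2 in 5 of 12 and Nr1d2 in 5 of 11. Astrocyte-like, precursor-like and committed precursor-like cells had 4, 3 and 1, all on the sex chromosomes. DESeq2 called 37 genes in all nuclei and 21 in thalamic-like neurons. Without wild-type female 6 and heterozygous-labelled female 5, edgeR called 79 in all nuclei and 53 in GABAergic-like neurons. Myt1l did not pass by sex, with log2 fold changes of -0.04 in all nuclei, -0.04 in GABAergic-like neurons, -0.05 in glutamatergic-like neurons outside the thalamus and 0.09 in thalamic-like neurons (adjusted p = 0.460). It stood at 0.31 in oligodendrocyte-like and 0.08 in precursor-like cells.

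By sex 24 of 145 list tests passed, and 12 held with an estimated correlation. Outside the lists of the sex chromosomes 13 passed, and 5 of 41 splits of the mice, the real one included, passed as many. The X-escape genes (8 of 10 past the threshold in all nuclei) and the Y-linked genes (4 of 4) held in all nuclei, the 3 neuron classes and oligodendrocyte-like cells, and the X-escape genes also in astrocyte-like cells. The 12 neuropeptide and hormone receptor genes measured in thalamic-like neurons were all lower in females (adjusted p = 0.00405; adjusted p = 0.0292 with an estimated correlation), 3 of them past the threshold adjusted over the list alone and 0 over all genes. The immediate early list was lower in females in all nuclei (19 of 23 genes, adjusted p = 3.14e-08; adjusted p = 0.0512 with an estimated correlation), in GABAergic-like neurons (13 of 16, 0.0117; 0.283) and in glutamatergic-like neurons outside the thalamus (12 of 14, 0.00392; 0.323). Thalamic neuron genes were higher in females in GABAergic-like (10 of 10, 0.00288; 0.184) and glutamatergic-like neurons outside the thalamus (9 of 9, 0.0117; 0.608), and myelin genes in all nuclei (20 of 20, 9.17e-06; 0.608). Oligodendrocyte-like cells, which make myelin, were 10.6% ± 4.44 of nuclei in females (n = 16) and 8.60% ± 4.16 in males (n = 20; permutation p = 0.171, adjusted p = 0.326). Potassium channel (16 of 23, 0.0401; 0.283) and synapse adhesion genes (20 of 28, 0.0416; 0.323) were higher in female thalamic-like neurons. In female oligodendrocyte-like cells glutamate receptor (15 of 16, 0.00679; 0.449), potassium channel (8 of 10, 0.0306; 0.607), synapse adhesion (17 of 19, 0.0227; 0.615) and imprinted genes (9 of 9, 0.0243; 0.541) were higher. The second p in each pair is the adjusted p with an estimated correlation.

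Whether the labelled genotype acted differently in the sexes was tested by the interaction, and no gene passed in any class in edgeR or DESeq2. At an unadjusted p under 0.05 edgeR counted 1171 genes in all nuclei, 1088 in GABAergic-like neurons, 762 in glutamatergic-like neurons outside the thalamus, 612 in thalamic-like neurons, 238 in oligodendrocyte-like, 25 in committed precursor-like, 79 in precursor-like and 112 in astrocyte-like cells. The gene nearest the threshold was Ube4b, a ubiquitin ligase, in precursor-like cells (log2 difference 1.39, SE 0.33, adjusted p = 0.0911), ahead of Sorbs2 at 0.73 and Zhx3 at 0.82 (0.516). The smallest p values in all nuclei belonged to Ercc6l2 at 0.29, Ly6e at -0.72 and Pcdhga7 at 0.41 (adjusted p = 0.755). In GABAergic-like neurons they belonged to Gm47591 at 0.64, Zcwpw2 at 0.49 and Abat, which breaks down GABA, at 0.26, and Tub at -0.46, D3Ertd751e at 0.49 and Tm6sf1 at 0.66 came first in glutamatergic-like neurons outside the thalamus. Sdc2 at 0.92, Fam76a at -0.64 and Gm44167 at -1.01 led in thalamic-like neurons, and Msmo1 at -0.90, Rp9 at -1.24 and AW554918 at 0.57 in oligodendrocyte-like cells. Wnk1 at -1.12, Mllt10 at 1.21 and Ppm1l at -1.23 led in committed precursor-like cells, and Nav3 at -0.71, Ube4a at 1.18 and Atxn2 at -0.75 in astrocyte-like cells. Myt1l had an interaction of 0.11 in all nuclei (adjusted p = 0.793) and of 0.21 in GABAergic-like neurons (adjusted p = 0.640). It was 0.010 in glutamatergic-like neurons outside the thalamus, -0.08 in thalamic-like neurons, -0.43 in oligodendrocyte-like and 0.21 in precursor-like cells. Of 148 list tests 3 passed, all in all nuclei, and 0 with an estimated correlation (adjusted p = 0.880 each). They were the thalamic neuron genes (10 of 10 negative, adjusted p = 0.00478), synaptic vesicle genes (16 of 24 negative, 0.0271) and neurodevelopmental disorder genes (25 of 31 positive, 0.0271).

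Immediate early genes, which neurons switch on within minutes of activity, were compared across classes, as the tissue was taken soon after the task. Fos stood at 7.45 ± 2.83 CPM (SD, n = 36) in glutamatergic-like neurons outside the thalamus, 5.88 ± 2.14 in GABAergic-like neurons, 4.53 ± 2.68 in thalamic-like neurons and 0.287 in oligodendrocyte-like cells. Egr1 (9.86 ± 3.38 CPM) and Junb (2.90 ± 1.33) were highest in GABAergic-like neurons, and Npas4 (3.97 ± 1.90) and Fosb (2.10 ± 1.42) in glutamatergic-like neurons outside the thalamus. Egr3 stood at 6.26 ± 4.79 CPM there and at 5.47 ± 2.63 in GABAergic-like neurons, an order that turned in nuclei thinned to equal depth. Thalamic-like neurons had the most Nr4a1, an orphan nuclear receptor, at 20.8 ± 4.79 CPM against 11.4 ± 3.18 and 9.75 ± 1.66 in the other two neuron classes, but little Egr3 (1.02 ± 1.35). Arc stood at 2.63 ± 2.18 CPM in glutamatergic-like neurons outside the thalamus and at 3.07 ± 3.79 in oligodendrocyte-like cells, from 30 counts in the latter. At 500 UMIs per nucleus, 0.342% of glutamatergic-like neurons outside the thalamus, 0.284% of GABAergic-like neurons and 0.235% of thalamic-like neurons had a Fos UMI, against 0.0104% of oligodendrocyte-like cells, which should lack it. Before thinning these were 1.83%, 1.15%, 1.58% and 0.0222%, at median depths of 2701, 2116, 3528 and 653 UMIs, and no nucleus was too shallow to be thinned.

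The sexes were then compared in the mean log2 level of the list. In all nuclei the mean of 23 genes was lower in females (difference -0.25, SE 0.07, two-sided permutation p = 0.00109, adjusted p = 0.00436 over 4 comparisons), and 13 of 16 females lay below the male median. The set test of the list missed the threshold with an estimated correlation (adjusted p = 0.0512). The list mean was tested by sex after the list had passed that test at the preset correlation. Its adjustment over 4 comparisons does not cover the 145 list tests by sex. Egr3 stood at 3.68 ± 2.49 CPM in females (n = 16) and 5.66 ± 2.50 in males (n = 20), and Egr1 at 7.47 ± 2.75 and 9.64 ± 2.51. Fosb stood at 1.03 ± 0.606 and 1.61 ± 0.765, and Fos at 5.32 ± 1.71 and 6.31 ± 1.69. Adjusted over the list alone, 6 genes passed: Gadd45b and Btg2, which restrain growth, at log2 fold changes of -0.81 and -0.44 (adjusted p = 0.0104 each), Egr3 at -0.68, Fosb at -0.65, Egr1 at -0.37 and the kinase Sik1 at -0.31. Over all genes none passed, the lowest adjusted p being 0.171. The mean differed by -0.14 (SE 0.06) over 16 genes in GABAergic-like neurons and by -0.25 (SE 0.10) over 14 genes in glutamatergic-like neurons outside the thalamus (permutation tests, adjusted p = 0.0289 each), where Btg2 and Egr3 passed over the list alone. It differed by -0.08 (SE 0.08) over 8 genes in thalamic-like neurons (permutation test, adjusted p = 0.387). By labelled genotype no immediate early gene passed over all genes in any class, with Fos at 0.17 (SE 0.12, adjusted p = 0.851) in all nuclei. Adjusted over the list alone 1 passed, Homer1 in thalamic-like neurons, which fell by 0.17 (SE 0.05, adjusted p = 0.0106).

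**Figure D4:**
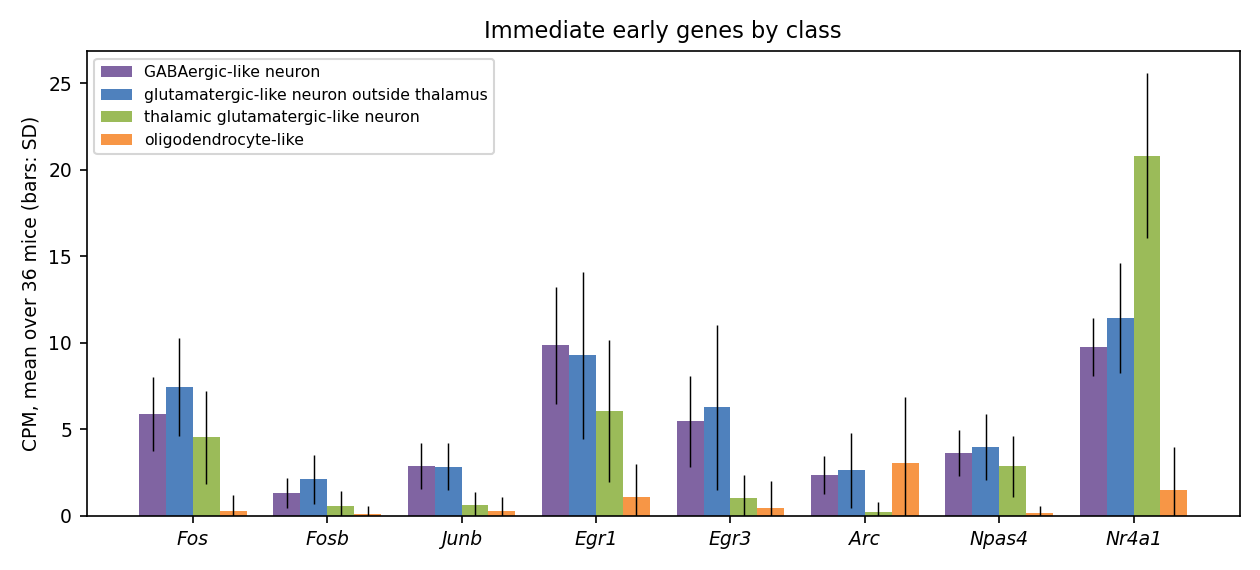
Levels of 8 immediate early genes in CPM in the neuron classes and oligodendrocyte-like cells, as means over 36 mice with SD. Nr4a1 is highest in thalamic-like neurons at 20.8 CPM, and Fos in glutamatergic-like neurons outside the thalamus at 7.45 CPM.

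Variation between mice was measured for each gene after sex and genotype, since the series concerns differences between individuals. The 3442 genes at 50 CPM or more in all nuclei had a median SD of 0.096 log2 units. Mid1, a ubiquitin ligase whose gene spans the pseudoautosomal boundary of the X chromosome in laboratory mice (X, 169685199 to 170005736), varied most. Its SD was 1.43, or 14.5 times that of genes of like level. It ranged from 32.4 to 2228 CPM with TMM scaling, which all CPM of single mice in this comparison carry. Its highest levels were those of the youngest wild-type mice, as given below, and age was not taken out of the spread. Several of the next genes mark thalamic-like clusters, such as Lef1 (SD 0.87, 12.1 to 225 CPM), Prkcd (0.78, 12.5 to 136 CPM) and Synpo2 (0.64), or striatal-like clusters, such as Rarb (0.71, 50.1 to 434 CPM), Gm10754 (0.87) and Rgs9 (0.61). Meis2 (0.63), Bcl11b (0.68) and Gm47283 (0.62) complete the first 10. With the share of thalamic neurons taken out, 4 of these 10 stayed among the first 10. Mid1 also led in GABAergic-like neurons (SD 1.49) and glutamatergic-like neurons outside the thalamus (1.37), where Nfib followed (0.81). In thalamic-like neurons Adamts19 (1.34, 0 to 260 CPM) and Rgs6 (1.05, 82.5 to 1673 CPM), which lead different thalamic clusters, varied most for their level. In oligodendrocyte-like cells 9630013A20Rik (1.35), a gene of young oligodendrocytes, led, and the glucocorticoid target Sgk1 had an SD of 0.53 and ranged from 195 to 1021 CPM. As lists, the immediate early, neuropeptide, hormone receptor, monoamine, myelin, mitochondrially encoded, stress and thalamic neuron genes each varied more than all but a few of 10000 random lists of like level (percentile 100 as rounded). Neurodevelopmental disorder genes (percentile 0.16) and X-escape genes (1.88) varied less than nearly all.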

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

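The tests of other splits of the mice, of depth and of single mice in the sex difference of immediate early genes, and of oligodendrocyte RNA in the thalamic genes were set before their own results were seen, those of the immediate early and thalamic genes after the data had been examined. With genes or lists of the sex chromosomes left out, only the split test in all nuclei was set so. The other tests of explanations here were chosen only after the result they concern was seen, as were the 3 patterns weighed.

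In thalamic-like neurons 26 genes differed by labelled genotype, among them lower Robo1, Ptprd, Epha6 and Unc13b and higher Cdh4 and Sorcs3. A different mix of thalamic clusters would vanish within clusters, but the fold within single clusters was 0.895 of the class fold at the median gene (quartiles 0.848 and 0.998), which argues against it. The 21 genes tested in more than 1 cluster had 1 sign in every one in 20 cases, though the clusters share the same mice. A covariate for depth left a median of 1.01 of the fold (0.931 to 1.13 over the 26 genes), and the oligodendrocyte RNA found in these nuclei (0.2999% in wild-type mice, 0.386% in mice labelled heterozygous) accounts for 0.00186 of the fold at the median gene, which argue against these as the cause. RNA of other cell types stays open, since only 4 oligodendrocyte markers could be tested there and their median fold of 0.22, nearer to 0 than the 0.29 of the called genes, decides nothing. A share under 0.05 was set beforehand to exclude chance, and 2 of 41 splits of the mice, the real one included, gave as many genes. So narrow a margin does not settle it, as the highest of the other splits called 56, above the real 26. That may point to a structure among the mice, which was not tested. The isolation batches, which the labels call balanced for sex and genotype but do not assign to mice, were not tested. The group sizes do not allow the same balance in every batch.

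Myt1l was not lower in the mice labelled heterozygous. If labels had been exchanged while true heterozygotes had 1 expressed copy, log2 Myt1l in neurons would span about 1 unit over the mice, and it spanned 0.418 (783 to 1046 CPM), so exchanged labels alone do not account for it. A different share of neuron classes does not either, since Myt1l was higher in 39 of 42 neuron clusters taken singly. That RNA of the altered allele is counted in full in nuclei may hold and cannot be told apart here, as 0 features of the matrices name an exon or an allele.

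Immediate early genes were lower in females than in males. Depth may be set aside, since with the median UMI count as a covariate the difference was 0.993 of its size, and so may a single mouse, since leaving out each mouse in turn kept at least 0.892 of it. A different cell makeup stays open. With the thalamic share as a covariate the difference in all nuclei was 0.915 of its size (-0.23, SE 0.07), but other shares were not taken out. The difference in single neuron classes was as low as 0.297 of that in all nuclei, in thalamic-like neurons, where 8 genes could be measured against 23. Over the same 8 genes it was -0.08 (SE 0.08) there and -0.12 (SE 0.05) in all nuclei, a ratio of 0.644 that the errors leave undecided. Over the same genes the ratio was 0.639 in GABAergic-like neurons and 1.06 in glutamatergic-like neurons outside the thalamus. Chance stays open too, since the list was taken up after it had passed among 145 list tests by sex. Outside the lists of the sex chromosomes, 5 of 41 splits of the mice, the real one included, passed as many lists. Sex itself, and how each mouse performed in the task before sampling, stay open and untested.

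Other splits of the mice into groups of the same sizes were used to ask which other counts exceed chance. By genotype, 1 of 41 splits, the real one itself, gave as many genes as the real one in all nuclei (2 genes, highest other 1). That is under the share of 0.05, but counts this small do not exclude chance, and leaving out 1 mouse at a time gave 0 to 5. In GABAergic-like neurons 3 of 41 splits reached the real count (1 gene, highest other 1), so chance is not excluded for Zbtb20. Where 0 genes passed by genotype every split reaches that count, 41 of 41, which shows nothing about chance; the highest other count was 0 in glutamatergic-like neurons outside the thalamus, 1 in oligodendrocyte-like, 1 in committed precursor-like, 2 in precursor-like and 1 in astrocyte-like cells. Summed over neuron clusters the genotype calls numbered 114, and 1 of 21 splits reached that, the real one, with 48 as the highest other. The real count lies above all others, but 21 splits can show no smaller share, so the margin does not settle chance. Thalamic-like clusters hold 63 of the 114 calls, so the sum is not separate from the thalamic class. The split with 48 was also the one with 56 genes in thalamic-like neurons.

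By sex, 1 of 41 splits, the real one, gave as many genes in all nuclei (27, highest other 0), in GABAergic-like neurons (23, 0), glutamatergic-like neurons outside the thalamus (15, 2), thalamic-like neurons (10, 1), oligodendrocyte-like (11, 2), precursor-like (3, 1) and astrocyte-like cells (4, 1). Genes of the sex chromosomes part the true sexes by construction, so these counts say little about chance. Off the sex chromosomes, 1 of 41 splits, again the real one, gave as many in all nuclei (12, highest other 0), GABAergic-like neurons (10, 0), thalamic-like neurons (3, 1), glutamatergic-like neurons outside the thalamus (3, 2) and oligodendrocyte-like cells (3, 2). These counts argue against chance in all nuclei and GABAergic-like neurons. In the other classes named the real count lies close to the highest other, which does not exclude chance. Precursor-like and astrocyte-like cells had 0 genes off the sex chromosomes (highest other 1 each), which every split reaches. In committed precursor-like cells 3 of 41 splits called as many as the 1 real gene, Xist, and the highest called 13, several times more. That may point to structure among those 20 mice, which was not tested. For the interaction the real count was 0 in every class, which all 31 of 31 splits reach, so this too shows nothing about chance. The highest of the others was 1 in all nuclei, 1 in GABAergic-like, 0 in glutamatergic-like neurons outside the thalamus and 1 in thalamic-like neurons. In glia it was 6 in oligodendrocyte-like, 32 in committed precursor-like, 1 in precursor-like and 2 in astrocyte-like cells. The 6 and 32 may again point to structure among the mice, which was not tested.

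Cluster sizes gave 0 calls by genotype and by sex, which all 100 of 100 splits reach and which shows nothing about chance. The highest of the others were 19 and 1, and the 19 may point to structure in how many neurons of each cluster a mouse gave, which was not tested. Gene lists by genotype passed 11 times, which 11 of 41 splits reached (highest other 26), and by interaction 3 times, which 21 of 31 reached (highest other 18). Chance is therefore not excluded for either, and both highest counts may point to correlated genes or structured samples, which was not tested. By sex 24 list tests passed, which 1 of 41 splits reached, the real one, with 20 as the highest other, but lists of the sex chromosomes part the true sexes by construction. Without these lists 13 passed, which 5 of 41 splits reached (highest other 17), so chance is not excluded for the other lists.

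A gap between 1 mouse and the rest of its group, of a size that chance gives in about 1 in 20 groups, appeared in 32 of 248 checks. The 62 values checked include genes picked for their spread or their calls in these mice, and values that restate one another. The 32 can therefore not be set against that rate. Most of the gaps fell on a pair of mice with little thalamus. Wild-type female 6 had 3.19% thalamic-like cells among its neurons (the others 12.6% to 22.004%), 2.30% among all nuclei (others 8.37% to 15.2%) and 50.1% GABAergic-like neurons (others 27.3% to 39.2%), Myt1l at 949 CPM in neurons (others 783 to 871), and in all nuclei Lef1 at 32.8 (others 123 to 224), Gm10754 at 138, Rarb at 193 and Rgs9 at 177 CPM. Its thalamic-like neurons had 6330411D24Rik at 0, Ptprd at 7634, Prkch at 276, Spon1 at 305 and Tox at 1015 CPM. In all nuclei heterozygous-labelled female 5 had Egr1 at 14.9, Npas4 at 5.28, Junb at 4.06 and Egr3 at 11.2 CPM. It had Rarb at 428 and Rgs9 at 282 CPM there. In its thalamic-like neurons Robo1 stood at 6127, Ptprd at 6961 and Spon1 at 53.8 CPM. This mouse had 1.76% thalamic-like cells among its neurons. It gave 2921 kept nuclei and wild-type female 6 gave 2913, so the thalamic-like levels of both rest on few nuclei. Whether sampling alone gives such gaps was not tested.

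Heterozygous-labelled male 9 stood apart in depth, with a median of 1455 UMIs per nucleus (others 1884 to 2337), and in thalamic-like Cdh4 at 349 and Spon1 at 123 CPM. Wild-type male 1 had Fosb at 4.14 CPM in all nuclei (others 0.680 to 2.35), and Cxxc1 at 15.1, Rbm20 at 55.0 and Epha6 at 1749 CPM in thalamic-like neurons. Wild-type male 6 had Apool at 23.3 CPM there (others 8.82 to 15.9), wild-type female 2 had Fos at 10.9 CPM in all nuclei (others 2.98 to 6.08), and wild-type female 9 had Mid1 at 929 CPM (others 41.8 to 89.8).

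The interaction of genotype and sex passed for 3 gene lists in all nuclei: synaptic vesicle genes and neurodevelopmental disorder genes (adjusted p = 0.0271 each) and thalamic neuron genes (adjusted p = 0.00478), none of them with an estimated correlation and, as given above, with chance not excluded. The share of thalamic-like nuclei crossed in the same direction as the thalamic list, at 7.62% in heterozygous-labelled females, 9.60% in heterozygous-labelled males, 9.68% in wild-type females and 7.55% in wild-type males. Barcodes above 10000 UMIs, which no comparison used, held 44.5% of all UMIs.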

How the results depend on the processing

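The fit without both mice that stood apart, wild-type female 6 and heterozygous-labelled female 5, nuclei of up to 20000 UMIs, each mouse left out in thalamic-like neurons, and covariates or mice left out for the immediate early list mean were chosen after seeing the data, though the depth covariate and mice left out for that mean were set before their own results were seen; the other alternatives here were planned. Of the values of the comparisons, 276 stayed within 1.5 times or on the same side of the threshold, 56 moved and 1 grew stronger. Of the named single genes 1800 values kept their side, 103 became weaker, 8 stronger and 8 turned direction, each of these 8 Myt1l. Comparisons without a call in either fit were tallied as staying, and genes that passed in neither fit as keeping their side. Genes of the sex chromosomes are among the named genes. The tallies therefore do not measure how firm the calls are. Fits of 1 sex have fewer mice, the fit without a filter tests more genes, and a set test with an estimated correlation asks for more; elsewhere the cause was not tested. Committed precursor-like cells could not be fitted at 1000 UMIs or 50 nuclei, a limit set by their depth and number.

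DESeq2 called 23 genes by genotype in all nuclei, 17 in GABAergic-like, 2 in glutamatergic-like neurons outside the thalamus and 46 in thalamic-like neurons, and 21 by sex in the latter. Without the filter genotype gave 6 in all nuclei, 3 in glutamatergic-like neurons outside the thalamus, 3 in oligodendrocyte-like cells and 55 in thalamic-like neurons, and sex gave 7 in astrocyte-like, 5 in committed precursor-like, 6 in precursor-like and 25 in oligodendrocyte-like cells and 68 in thalamic-like neurons. DESeq2's size factors in edgeR gave 1 by genotype in all nuclei. With age as a covariate it gave 1 there, 1 in oligodendrocyte-like and 1 in precursor-like cells, and with depth 1 in oligodendrocyte-like cells. With the thalamic share as a covariate genotype gave 24 in all nuclei and 1 in glutamatergic-like neurons outside the thalamus, sex gave 17 in thalamic-like neurons, and the interaction of Myt1l turned to -0.00064 in all nuclei and -0.027 in glutamatergic-like neurons outside the thalamus.

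Without the pair of mice that stood apart genotype gave 6 in all nuclei, 6 in GABAergic-like and 3 in glutamatergic-like neurons outside the thalamus, and sex gave 79, 53 in GABAergic-like and 25 in thalamic-like neurons and 10 in astrocyte-like cells. Females alone gave 0 by genotype in all nuclei, 0 in GABAergic-like and 4 in thalamic-like neurons, and males alone 0, 2 and 7; Myt1l turned to 0.068 in precursor-like cells in females and to -0.038 in GABAergic-like neurons in males. At 1000 UMIs sex gave 3 in oligodendrocyte-like and 1 in precursor-like cells, and Myt1l in the latter turned to 0.083 by genotype, -0.013 by sex and -0.14 in the interaction. With doublets kept genotype gave 1 gene in glutamatergic-like neurons outside the thalamus, and the Myt1l interaction there was -0.0018. The Myt1l difference in neurons alone, 50.4 CPM, passed the threshold.

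Cluster calls adjusted over all clusters numbered 59, and TMM factors gave 1 cluster by sex, cluster 10. Lists with an estimated correlation passed 0, 12 and 0 times by genotype, sex and interaction, and with fry 0, 13 and 0 times. Of the 10 most variable genes edgeR's dispersion kept 5 in thalamic-like neurons, 3 in oligodendrocyte-like, 4 in committed precursor-like and 5 in astrocyte-like cells, and the thalamic share kept 4 in all nuclei. Leaving out each mouse in turn gave 0 (without heterozygous-labelled female 4) to 5 genotype genes (without heterozygous-labelled female 5) in all nuclei, more than 1.5 times from the 2 of all mice in 26 of 36 cases, and 17 (without wild-type male 8) to 33 (without heterozygous-labelled female 5) in thalamic-like neurons, where 1 case moved by as much.

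With the mouse number as a replicate block, 11 of 20 named thalamic genes lost their genotype call, genotype gave 0 genes in all nuclei and 1 in glutamatergic-like neurons outside the thalamus, and sex 11 in astrocyte-like, 3 in committed precursor-like and 6 in precursor-like cells; the Myt1l difference over 16 pairs was 35.5 CPM (permutation p = 0.163). Whether the numbers pair the mice cannot be told from the correlations of same-numbered mice, which were not set against those of other pairs. These correlations were above 0.1 in 9 of 16 pairs across genotype (median 0.161, -0.544 to 0.534). Across sex they were above 0.1 in 8 of 16 (median 0.056, -0.413 to 0.851).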

Other observations

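Some cell populations have not been described above. Cluster 10, GABAergic-like neurons led by Nfib and Synpr, made up 3.04% of neurons in females and 2.25% in males (edgeR p = 0.00233, adjusted p = 0.121, above the male median in 15 of 16 females). Cluster 44, led by Esr2, Greb1 and Cyp19a1, the aromatase gene, made up 0.942% in females and 1.60% in males (p = 0.0173, adjusted p = 0.258). Cluster 50, led by Nos1, made up 2.01% and 2.98% (p = 0.0271). By labelled genotype, cluster 10 made up 2.89% in mice labelled heterozygous and 2.37% in wild-type mice, and cluster 50 made up 1.99% and 3.00% (adjusted p = 0.489 each). With TMM factors on the library size cluster 10 passed by sex (log2 fold change 0.62, adjusted p = 0.0482), and with thalamic neurons left out it did not (adjusted p = 0.0935). Without such factors none of these passed the threshold.

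The spread between mice was also ranked within glial classes. In committed precursor-like cells the myelin gene Mobp varied most between mice for its level (residual SD 1.065), and in oligodendrocyte-like cells 9630013A20Rik did (SD 1.35, 4.06 times that of genes of like level). In astrocyte-like cells the imprinted RNA Meg3 led (SD 0.87), and Mid1, with an SD of 1.00, was also among the first 10.

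Mid1 was looked at mouse by mouse after its values were seen, and so were Asmt, Tmem267 and Pcbd2, which were picked because they moved with it. Mid1 stood at 2172 CPM in wild-type male 5, 2037 in wild-type male 10 and 929 in wild-type female 9, and the next highest mouse, heterozygous-labelled female 4, had 97.9 CPM. In the same 3 mice, in that order, Asmt (X, 170672644 to 170678054) stood at 4.55, 4.50 and 1.45 CPM, with 1.69 in heterozygous-labelled male 5, Tmem267 (chromosome 13, 119488039 to 119611059) at 29.3, 34.3 and 16.7 CPM, with 9.24 in the next mouse, wild-type female 6, and Pcbd2 (chromosome 13, 55727368 to 55776830) at 40.8, 40.6 and 32.3 CPM, with 29.8 in the next, heterozygous-labelled female 2. The mice fall into separate groups for Mid1, so no correlation was computed. The 3 mice with high Mid1 were 56, 61 and 57 days old, in the order given. The other wild-type mice were 69 to 77 days old. Heterozygous-labelled males 8, 9 and 10, at 56, 54 and 61 days, did not share the high level. Whether Mid1 went with age among the wild-type mice was not tested.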
